A study of Caenorhabditis elegans with 6 samples.

How the data were processed

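The series holds 6 RNA-seq libraries of whole L1 larvae, 3 of a div-1(or148) strain and 3 labelled N2 wild type. Groups and replicate numbers were taken from the sample titles, and the replicates are independent only as far as the labels state it. The authors deposited 1 table of raw counts per feature, whole numbers that were not normalised. TopHat2 2.1.0, featureCounts 1.5.0 and DESeq2 1.8.1 are named, per the submitters' processing notes, without their options. The genome build and annotation behind the counts are not given in the sources used here, nor whether counting used strand. Per the labels' protocols, RNA ends were prepared for adapter ligation and libraries were made with a small RNA kit and sized for short inserts. The sample titles call the material mRNA. In the deposited counts, protein-coding genes took 95.3% of the gene counts in the mutant and 95.2% in the wild type. MicroRNA genes took 0.0512% and 0.0594%, and rRNA genes 0.521% and 0.600%. The values thus read as fragments mostly of protein-coding transcripts. How well other RNA classes and core histone transcripts were captured cannot be told from these sources. Short fragments are harder to assign among paralogs, so counts of family members that share sequence are uncertain.

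The table has 99774 features, of which 45836 are genes, 53925 are single repeat copies of 179 families and 13 are parts of a reporter construct. Of the gene rows, 44549 matched a gene of the Ensembl release 115 WBcel235 annotation by name or older name. That annotation was used for gene type, chromosome, relative position and exonic length. An rRNA gene and the repeat lying over it hold nearly equal counts, so a read may count for 2 overlapping features. Gene counts alone therefore set library sizes and normalisation, and construct and repeat rows were fitted with the same factors. The total count per library was 26392800, 25051167 and 26268345 in the mutant and 26068976, 27632878 and 25331475 in the wild type. Intervals and limits computed from counts cover counting error only.

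Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, the default expression filter by group, a robust quasi-likelihood fit on group alone and a two-sided quasi-likelihood test, with Benjamini-Hochberg adjusted p under 0.05. 16289 genes passed the filter. The biological coefficient of variation common to all genes was 0.224. CPM values use effective library sizes. DESeq2 1.42.0 and limma 3.58.1 served as alternatives. Construct rows and repeat families were adjusted among themselves.

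Before the data were examined, 38 gene lists, the rule for named genes, the tests and the alternatives were fixed; 37 lists had at least 5 tested genes. Lists were tested with camera on the edgeR object, two-sided, with an inter-gene correlation of 0.01, beside camera with the correlation estimated and fry, and p values were adjusted over the lists. Arms were the first and last 30% of each autosome, compared by Fisher's exact test. Genes are named if they are div-1 or daf-21, if they are among the 12 largest changes in either direction with a mean of at least 5 CPM and no overlap between groups, or if they lead a list, with up to 4 members for a list that camera placed apart and up to 3 past the threshold for others. Shares of counts were compared by exact permutation of 3 against 3 libraries over 20 assignments, where the smallest two-sided p is 0.1. A gene without counts in a group was bounded with 3 counts over that group.

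The alternatives were 3 other scalings, 2 other filters, a fit that was not robust, a replicate block, protein-coding genes only, removal of the 10 most abundant genes, each library left out, a test against a 2-fold change, DESeq2 and limma voom. Leaving out div-1 mutant library 1 and wild-type library 1 together was added after seeing the data, as were all fits of construct and repeat rows. On simulated counts for the 16289 genes of this comparison, with 50 genes changed at each size, the test recovered 2% of genes changed 1.5-fold, 34% at 2-fold, 88% at 4-fold and 100% at 8-fold, with 9 false calls among 121. Camera called 0 of 20 unshifted simulated lists. Genes were simulated independently of each other, so this does not check camera on lists whose members vary together, as the real ones do. The estimated correlation was 0.97 for ribosomal protein genes.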

Results

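Transcripts were counted in RNA from whole Caenorhabditis elegans larvae at L1, the stage at which the animal hatches. There were 6 libraries, 3 from a strain with the or148 allele of div-1 and 3 from worms that the titles call N2 wild type. The labels call the 3 libraries of each group biological replicates. Both strains carry a reporter in which the daf-21 promoter drives mCherry, a red fluorescent protein. The wild-type libraries also held counts of this construct, so their strain is not N2 without a transgene. div-1 encodes a subunit of the DNA polymerase alpha-primase complex, which starts DNA synthesis. The title of the series concerns impaired DNA replication and derepressed chromatin, so the comparison asks which transcripts differ between the mutant and the wild type. The total count per library lay between 25051167 and 27632878.

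The mutated gene itself was transcribed at a similar level in both groups. div-1 stood at 35.1 ± 8.45 CPM (counts per 1e6 counts; SD, n = 3) in the mutant and 32.7 ± 9.59 in the wild type, a log2 fold change of 0.10 (edgeR adjusted p = 0.915). or148 is a point allele, so this level does not check the mutation. The endogenous daf-21 gene, which encodes the chaperone HSP90, stood at 1784 ± 262 CPM in the mutant and 1610 ± 27 in the wild type, with a log2 fold change of 0.15 (edgeR adjusted p = 0.808).

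The reporter transcript was far higher in the mutant. The mCherry row held 599 ± 86 CPM (SD, n = 3) in the div-1 mutant and 55.7 ± 7.21 in the wild type. That is a 10.8-fold difference, with a 95% interval of 7.99 to 14.5 and an edgeR adjusted p of 1.2e-06 over the 13 construct rows. The row of the daf-21 promoter rose by 1.78 on the log2 scale, to 22.2 ± 1.93 CPM from 6.46 ± 0.672 (edgeR adjusted p = 2.42e-05). The 3' UTR row named after unc-54 rose by 1.01, to 11.5 ± 1.43 CPM from 5.69 ± 1.28 (edgeR adjusted p = 0.00736). The promoter and 3' UTR rows are named after endogenous genes, and their reads may be shared with those. Their fold changes therefore need not measure the reporter. Backbone and marker parts of the same construct did not pass the threshold. The ampicillin resistance row had a log2 fold change of 0.37 (edgeR adjusted p = 0.201), the plasmid origin 0.42 (edgeR adjusted p = 0.201), and the C. briggsae unc-119 marker 0.32 in one row and 0.31 in the other (edgeR adjusted p = 0.201 for both). The ratio of mCherry to ampicillin resistance counts was 3.78 ± 0.682 in the mutant and 0.455 ± 0.0617 in the wild type, with no overlap between groups (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The homology arms named after the ttTi5605 site had log2 fold changes of 0.62 and 0.60 (edgeR adjusted p = 0.0687 and 0.0745), and passed the threshold without div-1 mutant replicate 1. These rows were chosen after the table was seen. C47E8.4, a gene that overlaps the start of daf-21 in the WBcel235 annotation, was also higher, at 150 ± 32.8 CPM against 61.9 ± 10.3 (log2 fold change 1.28, edgeR adjusted p = 0.0348), and it was named after its value was seen.

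**Figure D1:**
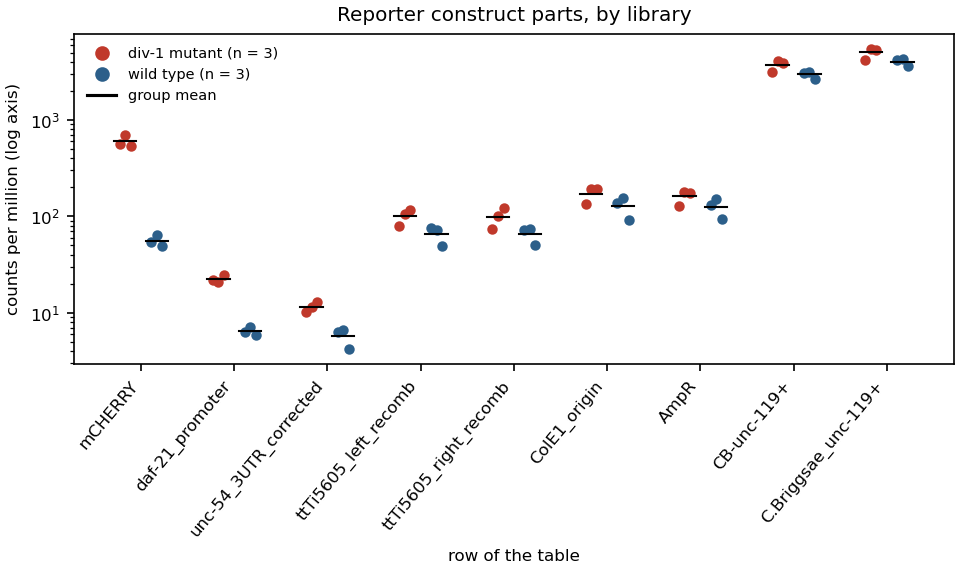
CPM (log axis) of the 9 reporter construct rows above 5 CPM in the mutant, with a point for each of the 3 div-1 mutant and 3 wild-type libraries and a bar for each group mean. The mCHERRY points of the mutant lie between 535 and 696, and those of the wild type between 49.2 and 63.4.

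Among the genes, 146 of 16289 tested were changed, and the calls were almost all upward. 144 were higher in the mutant and 2 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of the 144, 136 were at least 2-fold higher, and both lower genes were at least 2-fold lower. The 3 mutant libraries lay on one side of the 3 wild-type libraries for all 146, and for 17.9% of all tested genes, where chance gives 10%. Genes that vary together can move this share away from 10%. Of all tested genes without overlap, 1661 were higher and 1259 lower, a far more even split than that of the calls. The genes called higher were mostly of low level in the wild type, with a median of 3.21 CPM there against 14.6 CPM for all tested genes. Choosing genes for a rise favours a low wild-type level. The median log2 fold change of the 144 was 1.88. With the tested genes ranked by mean level over the 6 libraries in 4 equal groups, 45, 49, 35 and 15 were higher from the lowest group to the highest. At an unadjusted p under 0.05, the same groups held 626, 334, 238 and 148 genes higher and 49, 88, 163 and 98 lower. The upward excess thus lay mostly among genes of low level. Of the 144, 132 were protein-coding and 7 were pseudogenes. At an unadjusted p under 0.05, 1346 genes were higher and 398 lower. These counts moved with the processing, to 960 and 79 without div-1 mutant replicate 3, 1219 and 170 under the replicate block, 1549 and 183 with upper-quartile factors and 1718 and 145 with library size only. The count of 146 fell to 36 without div-1 mutant replicate 3, to 42 without wild-type replicate 1, to 46 without wild-type replicate 2, to 71 without div-1 mutant replicate 2 and to 91 without wild-type replicate 3, and DESeq2 called 483 genes. All 146 genes kept their sign in each alternative where they were tested, which their lack of overlap between groups largely fixed in advance.

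**Figure D2:**
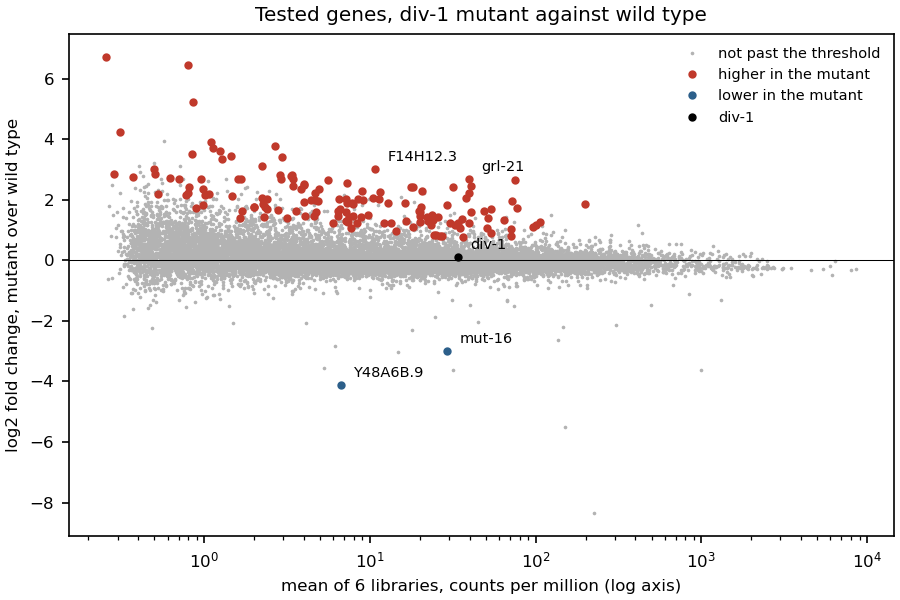
Log2 fold change of each of the 16289 tested genes, mutant over wild type, against its mean over the 6 libraries in CPM (log axis). Red points are the 144 genes called higher, blue points the 2 called lower and the black point div-1; for a gene with no count in the wild type, clec-209, the plotted fitted value is no bound.

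Of the 12 largest rises among genes with a mean of at least 5 CPM, that of F14H12.3 was the largest, from 2.34 ± 0.765 CPM to 19 ± 2.16 (SD, n = 3; log2 fold change 3.02 with SE 0.263, edgeR adjusted p = 0.00324). grl-21, of the hedgehog-related groundhog-like family, rose by 2.68 on the log2 scale, to 68.3 ± 5.46 CPM. C50F7.5 rose by 2.67, to 130 ± 29.4 CPM, and clx-1, of the collagen-like family, by 2.64. F08G5.6, currently named irg-4, a gene induced by infection, rose by 2.56. B0024.4, ZK970.7 and Y47H9C.1 rose by 2.47, 2.44 and 2.43. abu-10, of a family of proteins with prion-like repeats that is induced when the unfolded protein response is blocked, rose by 2.41. B0507.10, F16B4.4 and C30B5.6 rose by 2.3, 2.28 and 2.24. The edgeR adjusted p of these 12 lay between 0.00193 and 0.0336. Among the 6 fits that leave out a library, clx-1 was past the threshold only without div-1 mutant replicate 1, B0507.10 only without div-1 mutant replicates 1 or 2, and the other 10 in all 6.

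Both genes called lower had no overlap between the groups. mut-16, a scaffold protein of the foci where secondary small interfering RNAs are made, fell from 51.9 ± 1.46 CPM to 6.52 ± 1.84 (SD, n = 3), a log2 fold change of -2.99 with an SE of 0.217 (edgeR adjusted p = 0.002). Y48A6B.9 fell from 12.59 ± 1.09 CPM to 0.716 ± 0.135, a log2 fold change of -4.13 with an SE of 0.223 (edgeR adjusted p = 0.00151). Both were past the threshold in every fit that left out a library. Every mutant library has both the low mut-16 level and the div-1 allele. No other difference between the groups, in genes, gene lists or repeats, can therefore be assigned to the allele apart from mut-16. mut-16 lies on chromosome I and Y48A6B.9 on chromosome III, as div-1 does.

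**Figure D3:**
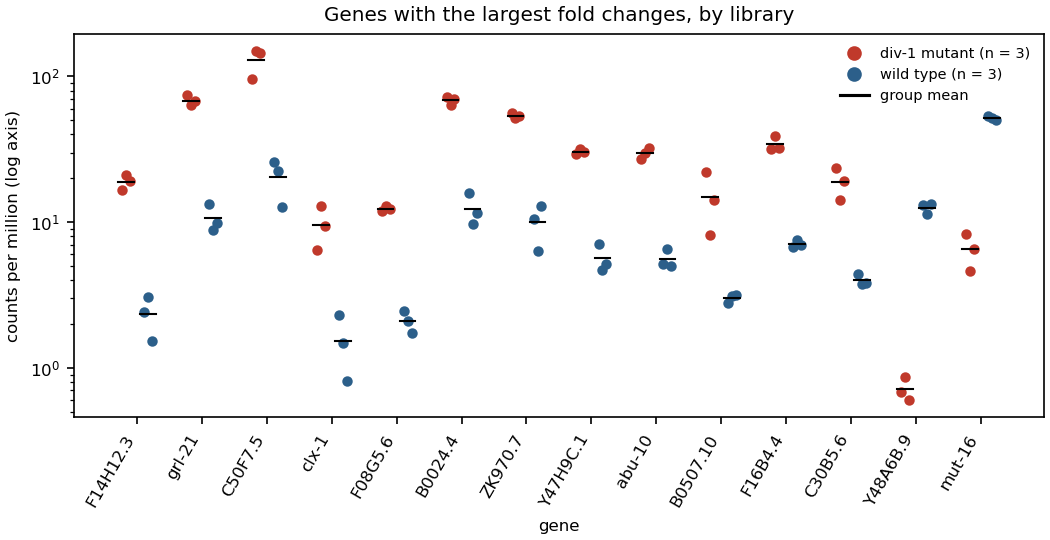
CPM (log axis) of the 12 genes with the largest rise and the 2 genes that fell, with a point for each of the 3 div-1 mutant and 3 wild-type libraries and a bar for each group mean. The mut-16 points lie between 4.66 and 8.34 in the mutant and between 50.6 and 53.5 in the wild type.

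Innate immunity effectors, which code for antimicrobial peptides, lysozymes and infection-response proteins, moved upward as a group. Of 49 tested members, 7 rose, none fell and 42 did not pass the threshold; adjusted over the list alone, 18 rose. The log2 fold change was positive in 42 of 49, with a median of 0.48. nlp-34, an antimicrobial peptide of the epidermis, rose by 1.62 to 29.9 ± 1.61 CPM (SD, n = 3; edgeR adjusted p = 0.00273). cnc-6, of the caenacin peptides, rose by 1.90 to 20.4 ± 1.14 CPM (edgeR adjusted p = 0.00636). The lysozyme lys-3 rose by 1.45 to 29.2 ± 0.687 CPM (edgeR adjusted p = 0.0115), and its call was lost without div-1 mutant replicate 3 and without wild-type replicate 2. The camera set test with its preset correlation placed the list above the other genes (adjusted p = 3.49e-17). The call was lost with an estimated correlation (adjusted p = 0.1). The fry test asks a different question, whether the list changed at all rather than whether it lay above the other genes, and gave an adjusted p of 0.0298.

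Stress and detoxification lists were placed higher by camera, with few single members past the threshold. In the cytosolic heat shock response, 1 of 26 members rose and 7 did when adjusted over the list alone (camera adjusted p = 0.000615, and adjusted p = 0.911 with an estimated correlation). The small heat shock gene hsp-16.41 rose by 1.45 (edgeR adjusted p = 0.0487) and was past the threshold only without wild-type replicate 3 among the 6 fits that leave out a library. hsp-70 had a log2 fold change of 1.64 (edgeR adjusted p = 0.0512), hsp-16.2 of 1.17 (edgeR adjusted p = 0.0614) and F44E5.4 of 1.17 (edgeR adjusted p = 0.0718), none past the threshold. Of 39 oxidative and xenobiotic response genes, 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0149, and adjusted p = 0.492 with an estimated correlation). That member was sod-5, a cytosolic superoxide dismutase, which rose by 2.82 to 5 ± 0.681 CPM (edgeR adjusted p = 0.00345). The list lost its camera call without wild-type replicate 1 (adjusted p = 0.12). None of 135 cytochrome P450 and UDP-glucuronosyltransferase genes passed the threshold of edgeR, also over the list alone, 24 had an unadjusted p under 0.05 upward and 1 downward, and 95 had a positive log2 fold change (camera adjusted p = 0.000377, and adjusted p = 0.371 with an estimated correlation). In the endoplasmic reticulum and mitochondrial unfolded protein response list, abu-10 and abu-8 rose, the second by 1.38 and, among the fits that leave out a library, past the threshold only without wild-type replicate 3, and adjusted over the list alone 3 of 27 rose, while camera did not place the list apart (adjusted p = 0.476).

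Camera placed some large gene families above the other genes, and others not: nuclear hormone receptors (229 tested, adjusted p = 0.829), cuticle collagens (126, adjusted p = 0.459) and MATH and BATH domain genes (66, adjusted p = 0.476) were not placed apart. In the F-box family, which adapts substrates to ubiquitin ligases, 3 of 297 members rose and 9 did when adjusted over the list alone; 220 had a positive log2 fold change, with a median of 0.31 (camera adjusted p = 1.02e-06, and adjusted p = 0.371 with an estimated correlation). fbxa-125 rose by 2.18, fbxa-100 by 1.44 and fbxa-142 by 1.40, each lost in all 6 fits that leave out a library. Of 493 chemoreceptor genes, 2 rose and 1 did when adjusted over the list alone (camera adjusted p = 0.0279, and adjusted p = 0.953 with an estimated correlation). The family lost its camera call without div-1 mutant replicates 2 or 3 or wild-type replicate 3 (adjusted p = 0.19, 0.17 and 0.28). srbc-15, annotated as a pseudogene, had 133 counts over the mutant libraries and 3 over the wild type, a ratio of 42.4 with a 95% interval of 14.2 to 208 for counting error alone. srj-4 rose by 1.84, a call lost with any library left out. Of 117 C-type lectin genes, 2 rose and 5 did when adjusted over the list alone (camera adjusted p = 0.0149, and adjusted p = 0.911 with an estimated correlation); the call was lost without div-1 mutant replicate 3 and without wild-type replicate 2 (adjusted p = 0.12 and 0.066). clec-41 rose by 1.61 to 73.1 ± 4.88 CPM (edgeR adjusted p = 0.00324). clec-209 had 40 counts in the mutant and 0 in the wild type and was at least 12.9-fold higher against a limit of 3 counts over the wild-type group, although its call was lost in all 6 fits that leave out a library. Of 12 tested sperm genes, 1 rose, spe-41 by 2.13 and past the threshold only without div-1 mutant replicates 1 or 2 among the fits that leave out a library, and 2 did when adjusted over the list alone (camera adjusted p = 0.0124, and adjusted p = 0.751 with an estimated correlation).

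**Figure D4:**
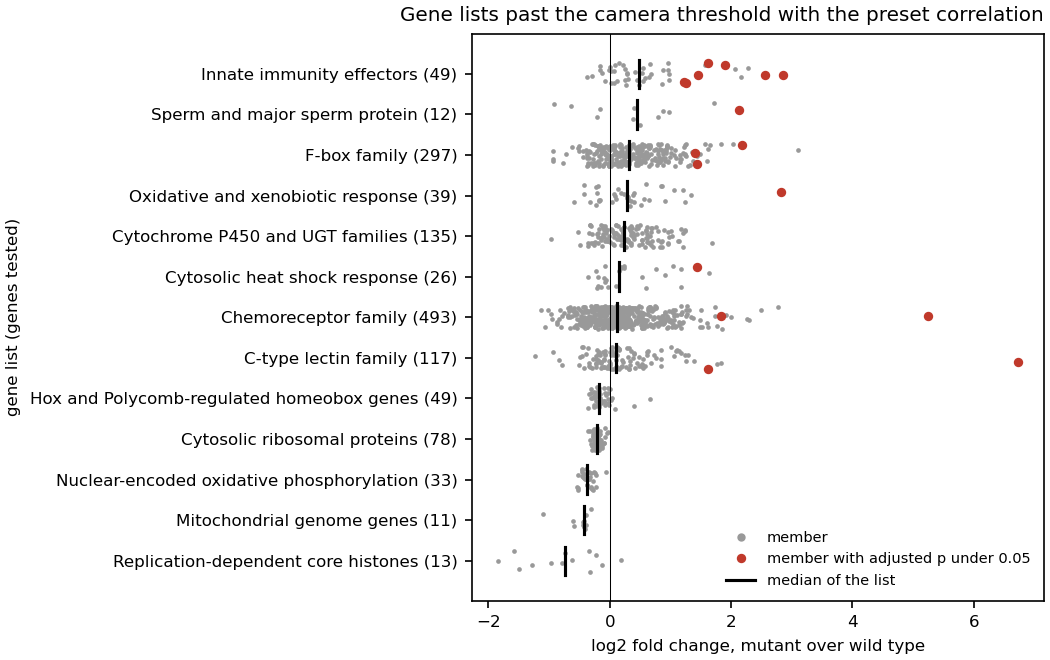
Log2 fold change of every tested member, mutant over wild type, in the 13 fixed lists that camera placed apart with the preset correlation, with the list median as a bar and the members past the edgeR threshold in red. The medians run from -0.73 for core histones to 0.48 for innate immunity effectors, and none of the 13 calls held with an estimated correlation; the point of clec-209 is a fitted value and no bound.

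Histone, ribosome and respiratory chain lists lay below the other genes, without any single member past the threshold. Of 64 replication-dependent core histones, only 13 had enough counts to be tested. These 13 had a median log2 fold change of -0.73, with 12 of 13 negative (camera adjusted p = 6.66e-05, and adjusted p = 0.492 with an estimated correlation). his-67 had a log2 fold change of -1.84 (edgeR adjusted p = 0.236) at 0.143 ± 0.105 CPM in the mutant. The more abundant his-41 had -0.34 (edgeR adjusted p = 0.429). Nuclear-encoded oxidative phosphorylation genes were all 33 negative, with a median of -0.37 (camera adjusted p = 1.96e-08, and adjusted p = 0.911 with an estimated correlation); gas-1, of complex I, had -0.46 and sdhd-1, of complex II, had -0.52. The 11 mitochondrial genome genes were all negative, with a median of -0.43 (camera adjusted p = 0.000336, and adjusted p = 0.911 with an estimated correlation), and the median became -0.19 without div-1 mutant replicate 1 (adjusted p = 0.051). All 78 ribosomal protein genes were negative, with a median of -0.22 (camera adjusted p = 1.5e-05, and adjusted p = 0.953 with an estimated correlation), and the median became -0.04 without div-1 mutant replicate 1 (adjusted p = 0.24). Hox and other homeobox genes had 43 of 49 negative, with a median of -0.18 (camera adjusted p = 0.011, and adjusted p = 0.911 with an estimated correlation); this call was lost without wild-type replicate 3 (adjusted p = 0.22). For these 5 lists, no member passed the threshold when adjusted over the list alone.

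Genes of the replication, repair and chromatin machinery had no member called. None passed the threshold of edgeR, over all genes or over the list alone, in the lists of DNA replication machinery (42 tested, median 0.05), DNA damage response and repair (51, median -0.00), cell cycle and mitosis (77, median 0.09), H3K9 methylation and heterochromatin factors (29, median -0.11), Polycomb and H3K27 or H3K36 factors (18, median -0.00), histone chaperones (19, median -0.08) or replacement and linker histones (15, median -0.22). Camera adjusted p values ranged from 0.179 to 0.827 over these lists, which does not show that they were unchanged: the log2 fold change was positive in 4 of 19 chaperones, 8 of 29 heterochromatin factors and 3 of 15 replacement and linker histones. At an unadjusted p under 0.05, the replication list had 3 members upward and none downward, and the repair list 3 and 2. In the small RNA pathway list, mut-16 fell and the Argonaute gene sago-2 rose by 1.87, the second past the threshold only without wild-type replicate 3 among the fits that leave out a library, and the list as a whole was not placed apart (camera adjusted p = 0.532). The remaining lists, of tissue and stage markers, metabolism and other families, were not placed apart by camera. By fry, microRNA genes were the only other list past the threshold beside innate immunity effectors (6 tested of 216, 3 positive, adjusted p = 0.0404). Their median log2 fold change was 0.04, with 1 member higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.664). Whether such a row counts the microRNA or a longer transcript over it was not tested. By fry, 12 lists passed when members were allowed to change in both directions. Among members of the remaining lists, whether or not fry called the list, ech-9 rose by 1.76, col-145 by 1.47, col-2 by 2.73 and the microRNA gene mir-5548 by 2.02. With a library left out, mir-5548 lost its call without div-1 mutant replicate 3 and wild-type replicates 1 and 2, ech-9 kept it only without div-1 mutant replicate 1, and the collagen genes lost it in every fit. Among 28 pharynx markers abu-8 rose, and 3 rose when adjusted over the list alone; 5 were higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.103). Intestine, body wall muscle, neuron, germline and maternal markers had no member past the threshold of edgeR.

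No excess of rising genes on chromosome arms or on the X chromosome passed a test, and an excess on arms was not excluded. In the WBcel235 annotation, 73 of 6988 tested genes on autosome arms were higher (1.04%), against 55 of 6559 in autosome centres (0.839%; two-sided Fisher's exact p = 0.248). On the X chromosome 14 of 2309 were higher (0.606%), against 128 of 13547 on autosomes (0.945%; two-sided Fisher's exact p = 0.12). Chromosome V held 55 of 3515 (1.56%), the highest share, and the others ranged from 0.474% on III to 0.965% on IV. This difference was not tested. Camera placed neither location set apart (adjusted p = 0.722 for both).

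Counts summed per repeat family, a choice made after the table was seen, gave 1 changed family of 155 tested. Mariner5_CE, a DNA transposon, rose from 18.7 ± 1.38 CPM to 63.6 ± 11.5 (SD, n = 3), a 3.40-fold difference with an edgeR adjusted p of 0.00104 over the families. A single copy, Mariner5_CE_48, held 60.9 CPM of this in the mutant, so the value stands mostly for 1 copy. The log2 fold change was positive in 130 of the 155 families, with a median of 0.21, while 10000 random lists of genes matched on expression had a median of -0.01, and 95% of them lay between -0.06 and 0.06. Such lists do not cover shifts that families share within a library: the SD of the family median over the 3 mutant libraries was 0.127, and 3 of the 10 splits of the 6 libraries, the real one included, put as large a share of the families on one side. LINE retrotransposon families were all 10 positive with a median of 0.51, LTR retrotransposons 24 of 29 with 0.39, DNA transposons 28 of 33 with 0.24, and Helitrons 4 of 7 with 0.02. At an unadjusted p under 0.05, 27 families were higher and 0 lower; the counts were 9 and 1 without div-1 mutant replicate 3, 15 and 0 without wild-type replicate 2, 17 and 0 under the replicate block and 34 and 0 without div-1 mutant replicate 2. Camera placed the families above the genes (adjusted p = 1.08e-05), and the call was lost with an estimated correlation (adjusted p = 0.386). Without div-1 mutant replicate 2, 7 families changed. Reads of repeats inside other transcripts could not be separated here.

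**Figure D5:**
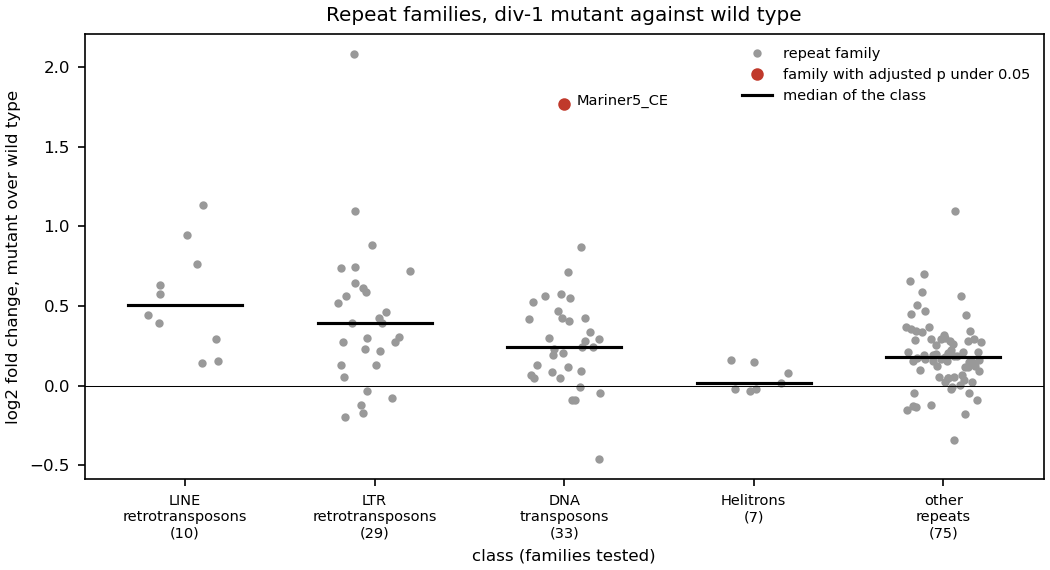
Log2 fold change, mutant over wild type, of each repeat family by class, with the median of each class as a bar; 1 family of rRNA repeats is not drawn. Mariner5_CE, in red, is the family past the edgeR threshold, and the medians are 0.51 for LINE and 0.02 for Helitron families.

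The composition of the libraries differed little between the groups. Protein-coding genes took 95.3% ± 0.119 of the gene counts in the mutant and 95.2% ± 0.0437 in the wild type (SD, n = 3; two-sided exact permutation p = 0.3). Mitochondrial genome transcripts took 0.623% ± 0.19 and 0.784% ± 0.0783 (exact permutation p = 0.2). Core histones took 0.029% ± 0.00279 and 0.0334% ± 0.00196 without overlap (exact permutation p = 0.1, the smallest possible, and 0.367 when adjusted over the 11 classes). tRNA genes took 0.000827% ± 3.61e-05 and 0.000648% ± 3.99e-05, and piRNA genes 0.053% ± 0.00269 and 0.0485% ± 0.00191, both higher in the mutant without overlap and with the same exact permutation p of 0.1. Correlations of log2 CPM over the tested genes ran from 0.970 to 0.992 within groups and from 0.961 to 0.986 between groups, so the libraries of a group were not closer to each other throughout. div-1 mutant library 1 lay farthest out on the first principal component, which held 42.1% of the variance.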

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

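Repeat copies counted singly were not used in the comparisons of genes or repeat families, and 10 of them were higher in the mutant than in the wild-type controls. The tests of explanations in this part were chosen after the results were seen, except the share of called genes near div-1 and the splits of the libraries. Of 1102 copies tested by edgeR, 11 changed, 10 upward and 1 downward, and 94 were higher and 12 lower at an unadjusted p under 0.05. CELE2_700 stood at 6.51 CPM in the mutant, Mariner5_CE_48 at 60.9, CELE14A_108 at 2.66, CEMUDR1_332 at 3.12, CeRep5_29 at 1.79, Tc1A_96 at 4.69, CELE11_183 at 0.775, CEMUDR1_110 at 1.42, CER16-1-LTR_CE_5 at 1.00 and CELE46A_419 at 1.23. Mariner5_CE_48 carries most of the count of the Mariner5_CE family, which stood at 63.6 CPM. With 10 splits of the 6 libraries no share under 0.05 is possible; the real split gave 11 changed copies and the highest other 0, and for families 1 against 0. For genes the real one gave 146 changed, 144 in one direction and 2 in the other, and the highest of the others 0, 0 and 0.

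The mCherry row was 10.8-fold higher in the mutant. More copies of the whole construct as the sole cause would raise its parts alike, but mCherry rose over the left homology arm, the nearest of 6 backbone and marker parts, by 2.80 on the log2 scale (SE 0.244). Reads of the endogenous daf-21 gene would not raise mCherry beyond daf-21, and the difference between their log2 fold changes was 3.28 (SE 0.253). The lower mut-16 level (log2 fold change -2.99) may contribute, and it cannot be told apart from the div-1 allele because every mutant library has both. An effect of the div-1 allele itself, or of where the construct sits in each strain, stays open and untested.

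For the 144 genes called higher against 2 lower, a uniform background such as genomic DNA would add no more per exonic megabase than to chemoreceptor genes; they gained 14617 CPM more (SE 572), a value raised by their having been chosen for a rise. Calls were then made without 1 mutant and 1 wild-type library, and the gain was taken from those 2 alone. Of 9 choices, 4 called at least 5 genes and 4 called none. In the former the called genes gained on average at least 21498 CPM per megabase more than chemoreceptor genes (SE 3282 over genes). That SE comes from 1 library per group and holds no spread between libraries, and the choices share libraries. Gains of this size in libraries left out of the calls argue against such a background as their cause. Protein-coding genes with a mean of 0.1 to 1 CPM summed to 1.32 times the wild-type level in the mutant and those of 10 to 100 CPM to 0.972 times, and the ratio of these factors was 1.36 (SE 0.0579), which 1 scaling factor per library cannot give. For the low genes in sum, other genes of 0.1 to 1 CPM gained 119.5 CPM per megabase and chemoreceptors 86.5, a difference of 33 (SE 25.5), but genes of at most 0.1 CPM, with the level taken from 1 wild-type library left out of the gain, gained less than those of 0.1 to 1 CPM for each of the 3 choices, by at least 92.0 (SE 24.4). This argues against a uniform background as the sole cause, if reads of both groups of genes are assigned equally well, which was not tested; a smaller background may contribute.

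mut-16 and Y48A6B.9 were the 2 genes called lower. Variation linked to div-1 is argued against for mut-16, which lies on chromosome I while div-1 lies on III, at a log2 fold change of -2.99. Y48A6B.9 lies 0.788 megabases from div-1 in the WBcel235 annotation, and linked variation could account for it. Called genes made up 0.572% of tested genes within 2 megabases of div-1 (4 of 699) and 0.981% of those elsewhere on autosomes (two-sided Fisher's exact p = 0.421), too few to decide. A sequence change in either gene was not tested, since the counts hold no sequence.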

How the results depend on the processing

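The construct and repeat values and the joint removal of 2 libraries were added after seeing the data. The 146 genes called here kept their sign under every alternative in which they were tested. None of them overlapped between groups, so this was largely fixed in advance. mCherry stayed past the threshold in every fit, with log2 fold changes of 3.3 to 3.53, and so did mut-16 and Y48A6B.9. The count of changed genes moved more: with no low-count filter 306 changed and 303 were higher, and with the stricter filter 91 and 89. Under the replicate block 52 changed and 50 were higher. The block pairs libraries by the number in the sample titles. In the submitters' column names the pair numbered 1 carries different numbers, and the other pairs carry the same. The deviations of same-numbered libraries correlated at -0.22, 0.50 and -0.31. The largest such value, 0.62, was between mutant library 1 and wild-type library 3. The closest pair between groups was mutant library 2 with wild-type library 2 (Pearson correlation 0.986). With so few libraries these values neither show nor exclude a pairing by number. Not every library correlated best with its own number. Against a 2-fold change, 26 changed and 24 were higher. For genes higher in div-1 mutant libraries DESeq2 called 474, for lower ones 9, and 483 in all, with no adjusted p for 8827 genes. With div-1 mutant library 1 and wild-type library 1 both left out, 68 changed and 65 were higher. Leaving out single libraries gave 36 to 116 changed and 34 to 113 higher, and fewer samples leave less power. Of 33 named genes past the threshold, 17 stayed past it in all 6 such fits.

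With an estimated correlation 0 gene lists were called, against 13. Changed repeat families numbered 2 with no filter, 2 with DESeq2 and 1 to 7 with a library left out. The median log2 fold change (chromosome location: autosome arms) was -0.0400 under the stricter filter, where camera turned downward, not past the threshold. div-1 itself, never past the threshold, turned negative at -0.28 with both libraries left out and ran from -0.11 to 0.35 with one left out. The difference in share of counts (RNA class composition: ribosomal proteins) ran from -2.17 to 0.0472 percentage points and that of snoRNA genes (RNA class composition: snoRNA genes) from -1.78e-05 to 0.000336, both changing sign. The cause of these moves was not tested.

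The test recovered 34% of simulated 2-fold changes, so the number of genes called is no count of the genes that differ.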

Other observations

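Most members of the pals family, genes of unknown biochemical role induced in the intracellular pathogen response, had a positive log2 fold change in the mutant, and few passed the threshold; this match and the tests of this part were chosen after values were seen, except the splits of the libraries for this family. A list of these genes was fixed beforehand, but the table carries their older names, and 36 rows were found through current symbols. Of 31 tested, 2 rose in edgeR over all genes, 13 rose when adjusted over the list alone, and 24 had a positive log2 fold change, with a median of 0.76. T27E7.6, currently pals-29, rose by 3.69 (edgeR adjusted p = 0.0172), and W08A12.4, currently pals-33, by 2.69 (edgeR adjusted p = 0.0348). B0284.1, currently pals-26, stood at 29.1 ± 14.6 CPM against 7.68 ± 0.431 (SD, n = 3; edgeR adjusted p = 0.0581). Camera gave p = 4.42e-14 with the preset correlation and p = 0.00257 with an estimated one; adjusted with the 37 other lists, the latter is 0.0514. Leaving out each library kept the median between 0.72 and 1.28 and the estimated-correlation p at 0.0121 or less, while the genes past the threshold ran from 0 to 4. At an unadjusted p under 0.05, 15 of the 31 were higher and 0 lower. The median gene, F15D3.8, currently pals-1, was not past the threshold (edgeR adjusted p = 0.685). Others lay near 0, such as C29F9.1, currently pals-22, at -0.07 and T17A3.2, currently pals-25, at -0.08. A part of the family, rather than all of it, may thus be raised, together with the innate immunity effectors. The 10 splits are too few for a share under 0.05; by camera with an estimated correlation the real one gave a p of 0.00257 and the smallest other 0.0880.

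Wild-type library 1 held 11 genes at a mean of at least 5 CPM that stood at least 8 times above all other libraries, and each of the other 5 libraries held 0. T22F3.11 stood at 1343 CPM there and at most 1.92 elsewhere, acs-2, an acyl-CoA synthetase, at 879 against at most 7.84, and sodh-1, an alcohol dehydrogenase, at 5161 against at most 199. hacd-1, of fatty acid oxidation, stood at 72.7 against at most 3.35. None of these was called changed, and 42 genes were called without this library.

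Genes called higher lay beside each other more often than placed at random on the same chromosome. Of 9 pairs of neighbouring tested genes both called higher, 8 did not overlap, and 100000 shuffles gave a mean of 1.27 such pairs (95% of shuffles between 0 and 4, permutation p = 4e-05). Such pairs include F01G10.5 with ech-9 and C49G7.10 with irg-2, and mir-5548 lies between K09F6.9 and K09F6.10, which were both higher. The pairs of mir-5548 with these neighbours come from a single locus. Shared regulation of neighbours may account for the 8 pairs, as may reads shared between paralogs, which was not tested.

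For the fixed lists, 7 of the 10 splits of the 6 libraries gave at least the 13 camera calls of the real one, and the highest other gave 23, so the splits of libraries that mix the groups called as many lists. For location sets the real split gave 0 calls and the highest other 0, with 10 of 10 splits at that count. For the share of repeat families on one side, a test chosen after the result was seen, the real split gave 83.9%, the highest other 85.2%, and 3 of 10 splits were as large.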
